A study of Mus musculus with 6 samples.

How the data were processed

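PolyA-selected RNA from mouse melanoma cells was sequenced as paired-end libraries, per the labels' protocols, from 3 samples of cells with a non-targeting control and 3 samples of cells in which Spp1 had been knocked out with CRISPR-Cas9. The labels call the samples of each group biological replicates and place all 6 in 1 batch. They give no cultures, clones or pools, so the p-values measure the spread between these samples and not between independently made knockout lines. The cell line label differs in every sample. It runs from B16F10 in control 1 to B16F15 in knockout 3 in sample order, and whether this is a numbering slip or names different cells is not stated. If the cells differed, that difference could not be separated from the knockout. The groups and replicate numbers were taken from the sample titles.

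The deposited table lists 19213 genes. Its values are signal values, reads per gene divided by 1 DESeq size factor per library, which the authors computed per the series' design text and the submitters' processing notes. Those notes name cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3, DESeq and the mouse build mm10, without giving a role or an order. The annotation release, the strand setting of the read counting and any filter on genes are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and genes that share over 20% of their exon length or sequence words with another gene are marked where their values are discussed. Every value in each deposited column was a whole multiple of the smallest value of that column (100% of values within 0.001 of a whole number), and that smallest value was taken as the worth of 1 read. On that basis no listed gene had fewer than 1 read in any library. A gene with 0 reads in a library is thus not in the table, and a gene switched fully on or off between the groups could be missing from all counts given here. The implied size factors differed by at most 0.837% from median ratios computed over the listed genes, after a common factor. All 6 columns of values were used.

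The recovered depth was 72717465 to 94314770 reads per library. In the column of Spp1 knockout 2 the worth of 1 read, 0.989, lies close to 1, and a check of units did not accept the recovery. Its values were whole multiples of that worth, as in the other columns. That library was still left out of the tests on recovered reads. Its depth, its reads of single genes and the read ratios that include it rest on that smallest value. Intervals on read ratios are exact 95% binomial intervals on the recovered reads and cover counting error only.

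The main test was fixed before the data were examined. The deposited values were transformed to log2(value + 1), genes with a value of at least 10 in at least 3 of the 6 libraries were kept, and knockout was compared with control in limma 3.58.1 (R 4.3.3) with a trended and robust variance, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on this scale, which understates the change of genes with few reads. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so none is reported for single genes. On simulated data made from the real means and depths, 50 genes were changed at each size, and those past the filter were scored. Every gene was given the same spread, near the common one measured. There limma recovered 66% of genes changed 1.2-fold, 84% of those changed 1.5-fold, 89.8% of those changed 2-fold and 100% of those changed 4-fold. Of its calls 4.5% were false. Real genes differ in spread and 63.0% of those tested changed, so these shares may not hold for the real test.

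At the same stage 36 gene lists were fixed, covering osteopontin receptors, genes beside Spp1, melanocyte and melanoma states, matrix, immune, signalling, cell cycle, stress and metabolic programmes, markers of other cell types and indicators of RNA quality. The 35 lists with at least 3 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list, and fry, were set to run beside it. Members were counted as past the threshold after adjustment over all tested genes and again adjusted over the list alone. Genes are named by a rule fixed in advance. It takes Spp1, the 10 genes higher and the 10 genes lower with the largest log2 change, and in each list up to 2 members higher and up to 2 lower with the largest change past the threshold, or the member with the highest mean where no member passed. The 10 and 10 had to reach a mean of 100 in the higher group, to have all knockout libraries on one side of all control libraries, and not to be predicted gene models. Genes named outside the rule are said to have been chosen after their values were seen.

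Gene positions, GC content and transcript lengths came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the listed identifiers 19121 matched it without version numbers and 13954 matched with the same version, so gene models can differ from those behind the deposited values. Shared sequence was measured as the share of 50-base words of a gene's longest transcript that occur in a transcript of another gene. After the data were seen, tested genes were placed in chromosome order, the median log2 change of the 25 tested genes on each side was computed, and chromosomes were divided into segments by binary segmentation (at least 20 genes, 200 permutations, p 0.01, log2 changes limited to 1 in size). On simulated data a planted shift ending at 60 Mb was placed at 59.2 Mb and no other segment moved. That shift was larger than most of those found in the real data. Genes outside it and outside a shifted gene list were left unchanged. The precision may therefore not hold for the real segments.

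Alternatives set beforehand were a pseudocount of 0.5 or 5, no filter on low values or a minimum of 50, TMM rescaling, equal totals, the replicate number as a block, sample quality weights, limma without trend and robust estimation, and leaving out each library in turn. edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0) were planned on recovered reads of all libraries. They were run on the 5 libraries whose recovery was accepted, a change made after the data were seen. In the same simulated data, with the same limits, edgeR on 5 libraries recovered 56% of genes changed 1.2-fold. It recovered 86% of those changed 1.5-fold and of those changed 2-fold, and 100% of those changed 4-fold, with 4.1% of its calls false. Added after the data were seen were the subtraction of the positional running median, the subtraction of a trend on GC content, transcript length and expression, a test against a change of 1.2-fold, camera with an estimated correlation in edgeR and after each of these subtractions, and 2 further gene lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.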

Results

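The transcriptome of mouse melanoma cells was compared between cells carrying a non-targeting control and cells in which Spp1 had been knocked out. The cell line label runs from B16F10, a metastatic melanoma line, in control 1 to B16F15 in knockout 3, a different label for each sample, and the sources do not say if the cells differed. Spp1 encodes osteopontin, a secreted phosphoprotein that binds integrins and CD44. Each group held 3 samples. The control libraries held 72717465, 84614609 and 94314770 reads in listed genes, and the knockout libraries held 75438190, 79930175 and 80206796. Libraries of one group correlated at r = 0.996 to 0.997 across genes on the log2 scale. Each pair differed by more than sampling noise (chi-square per degree of freedom 6.27 to 18.7), so none was treated as a second reading of the same library. This cannot show that the samples were grown separately. The common biological coefficient of variation was low, at 4.02% (edgeR, 5 libraries). The 10 most abundant genes took 5.85% to 6.62% of the reads of each library, and mitochondrially encoded genes took 2.75% to 3.04%. All values below are reads divided by the authors' size factors, called scaled reads.

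Spp1 was reduced in every knockout library. The gene (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050 on the plus strand of mm10) was read 143, 175 and 178 times in the control libraries and 2, 2 and 4 times in the knockout libraries. The scaled level was 150.2 ± 5.87 in control and 2.66 ± 1.08 in knockout (SD, n = 3 each), a log2 change of -5.41 ± 0.25 (SE, limma adjusted p = 8.98e-11). The ratio of knockout to control was 0.0178, with an exact 95% counting interval of 0.00765 to 0.0354. The control level was low for libraries of this depth. A predicted gene, Gm42793, overlaps 18.8% of the exon length of Spp1, and its reads could not be told apart from those of Spp1 without strand.

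**Figure D1:**
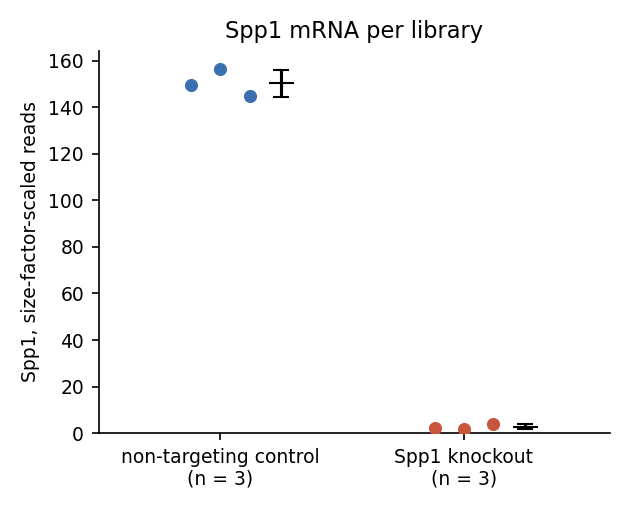
Spp1 in scaled reads (vertical axis, linear, from 0) for each of the 3 control and 3 knockout libraries, with points for libraries and a bar for the mean with its SD. The control libraries sit near 150.2 and the knockout libraries near 2.66.

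The knockout and control samples differed across most of the transcriptome, mainly by small amounts. Of 15307 genes tested, 9640 (63.0%) changed, 5266 being higher and 4374 lower in knockout (limma, adjusted p under 0.05). Of the changed genes 7087 (73.5%) moved by less than 1.5-fold. The larger number of higher genes depended on the scaling. With equal totals 4476 were higher and 5030 lower in knockout, and in edgeR on 5 libraries 4280 were higher and 4569 lower. At 2-fold or more the balance turned towards loss, with 249 genes higher and 835 lower, and at 8-fold or more 20 were higher and 69 lower. In 10275 genes (67.1%) the 3 knockout libraries lay wholly above or wholly below the 3 control libraries, where 10% is the share given by chance. The first principal component held 79.8% of the variance and the second 7.09%. When the test was made against a change of 1.2-fold, a choice made after the data were seen, 3749 genes passed (1581 genes higher in knockout and 2168 genes lower in knockout). Of the changed genes named below Acat2, Tipin, Pvr, Cd44, Itgb5, Ppm1k, Herc6, Herc3, Abcg2, Slc40a1, Tap1, Tcf7l2, H2-M3, Plvap and Esrp1 did not pass that test, nor did Bcl3, Dusp1, Hexa, Hist1h1c, mt-Rnr1 and mt-Atp6, which are named with the alternative settings. With a minimum of 50 scaled reads, 695 genes in place of 1084 changed by 2-fold or more.

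The genes that rose most ranged in control from nearly silent to clearly read, with means from 0.92 scaled reads for Tmem98 to 88.4 for Lgr6. Tmem98, a transmembrane protein gene, had 1 read in each control library and 381.8 ± 23.004 scaled reads in knockout (log2 change 7.64 ± 0.21, ratio 421 with a counting interval of 144 to 2042). Piwil2, which acts in the piRNA pathway of germ cells, rose from 23.03 ± 6.88 to 3610 ± 77.2 (log2 change 7.27 ± 0.19, limma adjusted p = 4.22e-09). Mrap, an accessory protein of melanocortin receptors, rose from 3.99 to 287.2 scaled reads. Pbxip1, Fam81a, Negr1, Brsk1, Ddx25, Lgr6 and Nipal4 followed, with log2 changes of 4.78, 4.56, 4.04, 3.84, 3.78, 3.38 and 3.14. Ddx25 encodes a testis helicase and Lgr6 a receptor for R-spondins. Brsk1 shares 25.7% of its exon length with Tmem150b and is uncertain for that reason.

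The genes lost in knockout included some with high levels in control. Gdf9, a TGF-beta family factor best known from oocytes, fell from 9824 ± 193 to 32.7 ± 4.99 scaled reads (SD, n = 3; log2 change -8.20 ± 0.09, limma adjusted p = 5.72e-17). Map7d2, a microtubule-associated protein gene, fell from 1817 ± 59.3 to 20.04 ± 6.82 (log2 change -6.48 ± 0.18). Col6a3, a collagen VI chain, fell from 812.9 ± 20.3 to 11.5 ± 7.97, and Bche, butyrylcholinesterase, from 577.2 ± 20.003 to 8.38 ± 0.899. Mlip, Cpa6, Zic1, Bcan, Spp1 itself and Mndal completed the 10, with log2 changes of -5.91, -5.82, -5.70, -5.44, -5.41 and -5.37. Zic1 is a neural crest and neural transcription factor, Bcan the proteoglycan brevican, and Mndal an interferon-inducible gene that shares 27.2% of its 50-base words with other genes. Spp1 was 1 of the 69 genes lower by at least 8-fold.

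**Figure D2:**
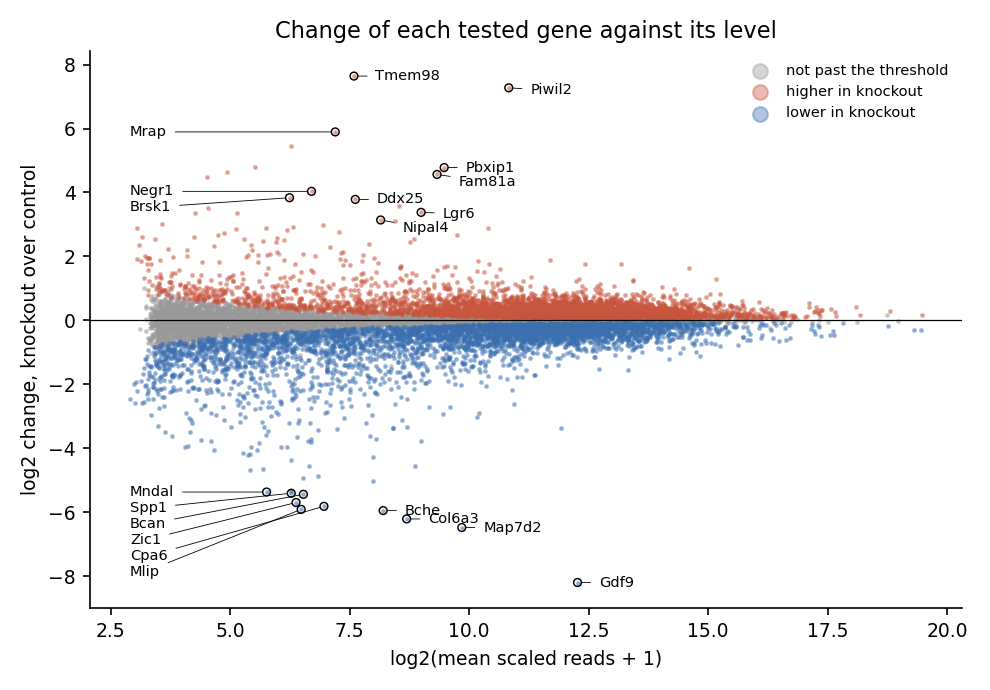
Log2 change of knockout over control (vertical axis) against log2 of the mean scaled reads plus 1 (horizontal axis) for the 15307 tested genes, 1 point per gene, coloured by direction where past the threshold. Circles mark Spp1 and the named genes with the largest changes, from Gdf9 at -8.20 to Tmem98 at 7.64.

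Interferon-stimulated genes were lower in knockout as a group. Of 38 tested members 33 fell, 5 did not pass and 0 rose, also 0 at an unadjusted p under 0.05 in limma and 0 in edgeR and DESeq2 on 5 libraries. The median log2 change was -1.10. Ifit1, an antiviral RNA-binding protein, fell from 3347 ± 126 to 546.9 ± 37.2 scaled reads (SD, n = 3; log2 change -2.61 ± 0.05). Irf7, a master transcription factor of the interferon response, fell from 31.7 ± 14.5 to 1.00 ± 0.04 (log2 change -3.94, or -2.54 with a pseudocount of 5). The list stood apart from other genes in camera (adjusted p = 5.69e-12) and not with an estimated correlation (adjusted p = 0.389 with an estimated correlation). Macrophage and myeloid markers were also lower in 4 of 5 tested genes, but that list did not pass camera (adjusted p = 0.0753). A link between these lists was not tested. Lyz2, which lies on chromosome 10, fell from 163.3 ± 4.31 to 36.6 ± 7.49 and S100a8 from 32.2 ± 7.72 to 8.04 ± 1.85 scaled reads, while Csf1r and Fcgr3, below the filter, stood at 2.30 and 1.22 in control and 2.96 and 1.33 in knockout.

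Genes of immune recognition and secreted immune signals were also lower. In the list of immune checkpoint and NK cell ligands 10 of 14 tested genes fell and 2 rose (camera adjusted p = 0.00331; adjusted p = 0.495 with an estimated correlation). Ceacam1, an inhibitory adhesion receptor, fell by 4.35 on the log2 scale, and H60b, a ligand of the activating receptor NKG2D, fell by 3.13. Pvrl2 and Pvr, nectin family ligands, rose by 1.06 and 0.20. Once the running median of neighbouring genes on the chromosome was subtracted, below called net of the neighbours' median, Pvr stood at 0.035 and no longer passed (limma adjusted p = 0.499). Of the members of this list 4 lie on chromosome 10, and all 4 fell. Ceacam1 shares 49.5% of its 50-base words with another gene. Among cytokines, chemokines and colony-stimulating factors 13 of 19 fell and 3 rose (camera adjusted p = 0.00547; adjusted p = 0.389 with an estimated correlation), a count that includes Spp1. The median of this list was -0.59, and -0.37 with no filter on low values. Ccl5, a T cell chemoattractant, fell from 757.3 ± 18.2 to 74.1 ± 7.95 scaled reads (SD, n = 3). Tslp rose by 1.24 and Ccl27a by 0.69 on the log2 scale, the latter sharing 69.2% of its words with another gene. Of 21 genes of MHC class I antigen presentation 11 fell and 6 rose, with H2-T23 at -2.99, Nlrc5 at -1.94, Tap1 at 0.62 and H2-M3 at 0.47, and the list did not pass (camera adjusted p = 0.160). The call of H2-M3 was lost without control 3, knockout 1 or knockout 2 (limma adjusted p = 0.176, 0.133 and 0.0881), with equal totals, in edgeR and DESeq2, without trend and robust estimation and net of the neighbours' median (adjusted p = 0.0616, 0.118, 0.249, 0.0580 and 0.0722).

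Cholesterol synthesis genes fell together. Of 25 tested members 19 fell and 2 rose, with a median log2 change of -0.54 (camera adjusted p = 8.97e-08; adjusted p = 0.495 with an estimated correlation). Sqle, squalene epoxidase, fell from 8681 ± 213 to 3964 ± 150 scaled reads (SD, n = 3; log2 change -1.13 ± 0.04), and Fdft1, squalene synthase, fell by 1.09 on the log2 scale. Acat2 rose by 0.23 on the log2 scale. It lies in a segment of chromosome 17 with a raised median and shares 45.9% of its words with another gene. It stood at -0.30 net of the neighbours' median.

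Genes of S phase and DNA replication were slightly higher in knockout. Of 39 tested members 31 rose and 2 fell, with a median log2 change of 0.21 (camera adjusted p = 2.93e-05; adjusted p = 0.543 with an estimated correlation). Cdt1, a licensing factor, rose from 6546 ± 330 to 10310 ± 408 scaled reads (SD, n = 3), and Ccne1, cyclin E1, rose by 0.49 on the log2 scale. Prim1 and Tipin fell by 0.36 and 0.32, and both lie on segments with a lowered median, on chromosomes 10 and 9. They stood at 0.30 and 0.018 net of the neighbours' median. Of 41 genes of G2 and M phase 21 rose and 11 fell (camera adjusted p = 0.658), against 15 and 14 with equal totals and 14 and 12 in edgeR on 5 libraries, with Ccnf at 0.62, Psrc1 at 0.45, Cdk1 at -0.70 and Ccnb2 at -0.48. All of these lie in shifted segments. They stood at 0.079, 0.91, -0.11 and -0.21 net of the neighbours' median, where Ccnf no longer passed (limma adjusted p = 0.0820).

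Targets of p53 were higher. Of 29 tested members 20 rose and 3 fell, with a median log2 change of 0.34 (camera adjusted p = 0.00241; adjusted p = 0.389 with an estimated correlation). Ddit4l, an inhibitor of mTOR signalling, rose from 178.9 ± 1.52 to 570.5 ± 23.7 scaled reads (SD, n = 3), and Perp, a desmosomal and apoptosis gene, rose by 1.26 on the log2 scale from a low level of 13.3. Sesn1 on chromosome 10 and Rrm2b on chromosome 15 fell by 0.92 and 0.54, and stood at -0.30 and -0.28 net of the neighbours' median.

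The list of epithelial-mesenchymal transition genes was lower, with 13 of 19 tested members falling and 1 rising (median log2 change -0.35, camera adjusted p = 0.00229; adjusted p = 0.495 with an estimated correlation). Without control 1 the median was -0.54. Acta2, smooth muscle actin, fell from 136.3 ± 11.5 to 7.98 ± 1.74 scaled reads, and S100a4, a mesenchymal marker that shares 56.3% of its words with another gene, fell by 3.82 on the log2 scale. The epithelial cadherin Cdh1 fell by 2.27, and the neural cadherin Cdh2 rose by 0.81. Of 36 genes of hypoxia and glycolysis 20 fell and 7 rose (median -0.32, camera adjusted p = 0.00241; adjusted p = 0.901 with an estimated correlation), and 4 of those that fell lie on chromosome 10. Ddit4, an mTOR inhibitor induced by low oxygen, fell from 3169 ± 520 to 937.4 ± 170 and Aldoc by 1.33 on the log2 scale. Eno2 and Pfkp rose by 1.11 and 0.82. Ddit4 fell by 1.76 on the log2 scale and stood at -1.13 net of the neighbours' median.

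**Figure D3:**
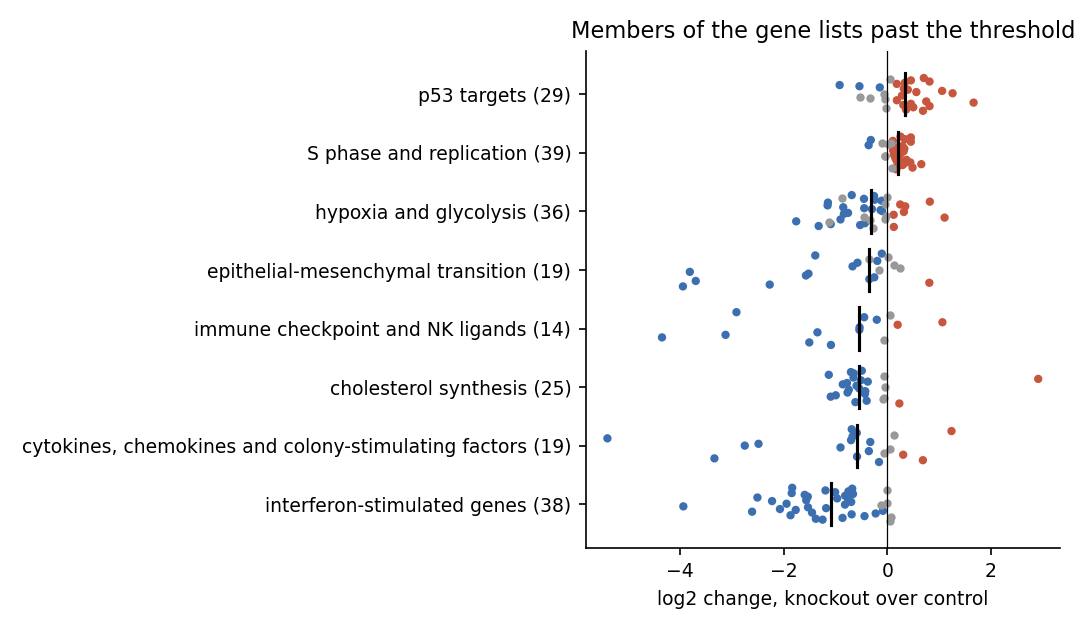
Log2 change of knockout over control (horizontal axis) for each tested member of the 8 gene lists past camera's threshold with the preset correlation (vertical axis, with the number of tested members in brackets). Each point is a gene, coloured where past the threshold in limma and grey where not, and black bars are medians, from -1.10 for interferon-stimulated genes to 0.34 for p53 targets.

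With the preset correlation 8 of 35 lists passed, 6 lower and 2 higher. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. Fry, which asks whether the members of a list move one way on balance without comparing them with other genes, passed 23 lists, all 8 among them. Camera with the preset correlation also called 4 to 15 lists in the 9 other ways of dividing the 6 libraries into 3 and 3, so the number of lists called does not separate the real grouping from others. Adjusted over the list alone, the counts of members were as given for every list except S phase (32 rose and 3 fell), hypoxia and glycolysis (21 fell), NRF2 and iron handling (8 rose), apoptosis regulators (11 fell) and replication-dependent histones (0 fell).

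The melanocytic programme did not shift as a group. Of 22 tested genes of melanocyte differentiation and pigment 9 rose and 7 fell, with a median of 0.0018, a mean of -0.39 and a camera direction of lower (adjusted p = 0.878). The median was below 0 with TMM rescaling, with equal totals, in edgeR, net of the neighbours' median and after the trend on GC content, length and expression was subtracted (-0.018, -0.047, -0.035, -0.016 and -0.040), and the camera direction was higher without control 1. Mreg and Gpnmb, a melanosomal glycoprotein, rose by 0.42 and 0.41 on the log2 scale, while Bcan and the pigment regulator Irf4 fell by 5.44 and 2.19. Of 15 genes of the undifferentiated or invasive melanoma state 4 rose and 7 fell (camera adjusted p = 0.426), Sox9 and Cyr61 by 1.46 and 0.59 upwards, Aqp1 and Thbs2 at -1.61 and -1.59. Among osteopontin receptors 5 of 9 rose and 4 fell, with a median of 0.08, a mean of -0.39 and a camera direction of lower (adjusted p = 0.658). The median turned to -0.15 with no filter on low values (10 genes), and was 0.034 with equal totals, 0.046 in edgeR and 0.0083 net of the neighbours' median. With equal totals, with TMM rescaling, in edgeR and in DESeq2 4 rose and 4 fell. Itgb5 and Cd44 rose by 0.23 and 0.21 (Itgb5 by 0.15 after a trend on GC content, length and expression was subtracted), and Itga8 and Itga5 fell by 1.64 and 1.57. In the list of genes near Spp1 3 of 10 rose and 6 fell (camera adjusted p = 0.426), but 4 of its members, Ppm1k, Herc6, Herc3 and Abcg2, lie on chromosome 6 in mm10 and are not neighbours of Spp1 there. Sparcl1 and Ppm1k rose by 0.47 and 0.19, and Hsd17b11 and Nudt9 fell by 1.02 and 0.40. Nudt9 shares 35.7% of its exon length with Gm43545, and Herc6 23.8% of its words with another gene. Herc6, Herc3 and Abcg2 were named after their values were seen, for their position.

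Matrix genes changed strongly in both directions. Of 27 tested extracellular matrix genes 7 rose and 12 fell (camera adjusted p = 0.426). The chains of collagen I parted, Col1a2 rising from 133.5 ± 9.54 to 778.6 ± 52.0 scaled reads and Col1a1 falling from 489.7 ± 61.2 to 36.8 ± 5.27 (SD, n = 3). Sparc rose by 1.30 on the log2 scale and Col6a3 fell by 6.21. Among 23 matrix proteases and inhibitors 10 rose and 8 fell (camera adjusted p = 0.775). With equal totals 8 rose and 9 fell, and in DESeq2 on 5 libraries 7 rose and 8 fell. Serpine2 rose from 787.8 ± 21.8 to 1812 ± 66.5 scaled reads and Mmp17 by 0.96 on the log2 scale, and Plat and Mmp11 fell by 1.08 and 0.92. Mmp11 stood at -0.36 net of the neighbours' median, and Mmp17 did not pass in DESeq2 (adjusted p = 0.0876). Of 20 TGF-beta and SMAD targets 4 rose and 13 fell (camera adjusted p = 0.121), with Ctgf at 0.66, Ski at 0.65, Col1a1 at -3.70 and Ltbp1 at -2.85. Ctgf, which shares 23.2% of its exon length with Gm15270, stood at 1.17 net of the neighbours' median.

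Signalling lists did not pass camera on the deposited values. Of 24 genes of MAPK pathway output 13 rose and 5 fell (adjusted p = 0.121), with Etv5 at 1.00, Spry4 at 0.97, Spry1 at -0.71 and Phlda1 at -0.54. Etv5 shares 26.8% of its words with another gene, and Spry1 and Phlda1 share 24.4% and 33.0% of their exon length with Gm42922 and Gm28592. Spry1 and Phlda1 stood at -0.42 and -0.040 net of the neighbours' median, where Phlda1 no longer passed (limma adjusted p = 0.504). YAP and TEAD targets had 8 of 18 higher and 7 lower (adjusted p = 0.658), with Ajuba at 0.71 and Gadd45b at -1.60. Gadd45b lies on chromosome 10, and the running median of its neighbours was -0.52. PI3K, AKT and FOXO targets had 5 of 20 higher and 10 lower (adjusted p = 0.217), with Igf1r at 0.69 and Pik3ip1 at -1.92. NF-kappaB targets had 5 of 19 higher and 8 lower (adjusted p = 0.658), with Sod2 at 0.76 (0.24 net of the neighbours' median) and Ccl5 at -3.34. AP-1 and immediate early genes had 6 of 23 higher and 8 lower (adjusted p = 0.778), with Btg2 at 0.50 and Ier5 at -0.62. Wnt and beta-catenin targets had 5 of 10 higher and 3 lower, with a median of 0.14, a mean of -0.02 and a camera direction of higher (adjusted p = 0.658), with Tcf7l2 at 0.48 and Tcf7 at -0.81. The median of this list was 0.014 with no filter on low values (15 genes), 0.27 with a minimum of 50 scaled reads (9 genes), 0.093 with equal totals and 0.23 net of the neighbours' median.

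The remaining stress and metabolic lists did not pass camera. The unfolded protein and integrated stress response had 13 of 34 genes higher and 16 lower (adjusted p = 0.426), against 9 and 19 with equal totals and in edgeR, with Ppp1r15a at 0.54 and Ddit3 at -1.70. Ddit3 lies on chromosome 10, and the running median of its neighbours was -0.48. NRF2 and iron handling had 7 of 23 higher and 11 lower (adjusted p = 0.426), with Slc40a1 at 0.34 and Gpx4, the phospholipid peroxidase that guards against ferroptosis, at -1.11. Gpx4 lies on chromosome 10, stood at -0.55 net of the neighbours' median and shares 61.7% of its words with another gene. Autophagy and lysosome genes had 11 of 33 higher and 11 lower, with a median of -0.03 (-0.0098 with sample quality weights to -0.079 with equal totals), a mean of 0.0034 and a camera direction of lower (adjusted p = 0.660), against 9 and 15 with equal totals and 7 and 12 in edgeR, with Tfeb at 0.69 and Ctsa at -0.35. Apoptosis regulators had 6 of 24 higher and 9 lower (adjusted p = 0.482), with Bak1, which shares 25.5% of its exon length with Ggnbp1, at 0.49 (0.13 net of the neighbours' median) and Casp12 at -3.84. Oxidative phosphorylation had 13 of 43 higher and 15 lower (adjusted p = 0.591), against 12 and 19 with equal totals and 9 and 15 in edgeR. Ndufb10 on chromosome 17 stood at 0.65 and Ndufs7 on chromosome 10 at -0.62, and net of the neighbours' median at 0.095 and -0.056, where Ndufs7 no longer passed (limma adjusted p = 0.450). Ribosomal protein genes had 21 of 44 higher and 8 lower (adjusted p = 0.591), a balance that turned to 9 higher and 11 lower with equal totals and 7 higher and 9 lower in edgeR on 5 libraries. Rps2 on chromosome 17 stood at 0.55 and Rps15 on chromosome 10 at -0.62, and they share 71.3% and 31.5% of their words with other genes. Net of the neighbours' median they stood at 0.0050 and -0.070 and no longer passed (limma adjusted p = 0.918 and 0.140).

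No list of markers of other cell types or of RNA quality passed camera. Of 5 tested fibroblast markers 1 rose and 3 fell (adjusted p = 0.426), Col1a2 at 2.54, Col1a1 at -3.70 and Pdgfrb at -1.36. Of 5 macrophage and myeloid markers 4 fell and 0 rose, also 0 at an unadjusted p under 0.05 in limma and 0 in edgeR and DESeq2 (camera adjusted p = 0.0753). Of 4 endothelial markers 2 rose and 2 fell, with a median of -0.44, a mean of 0.08 and a camera direction of lower (adjusted p = 0.857). The median was -0.14 with no filter on low values (5 genes) and turned to 0.44, with a camera direction of higher, with a minimum of 50 scaled reads (3 genes). In edgeR the direction was also higher, and with equal totals, in edgeR and in DESeq2 1 rose and 2 fell. The call of Plvap, 1 of those that rose, was lost without any library but control 1 (limma adjusted p = 0.0548 to 0.197). Vwf rose from 72.1 ± 1.26 to 622.4 ± 25.6 scaled reads and Egfl7 fell from 1318 ± 21.1 to 529.1 ± 36.9. Of 3 epithelial markers 2 fell (camera adjusted p = 0.426), against 1 in edgeR and 1 in DESeq2 on 5 libraries. Cdh1 fell by 2.27 on the log2 scale and Esrp1 fell from 15.4 ± 2.54 to 7.25 ± 5.63 scaled reads. The call of Esrp1 was lost without control 1, control 3, knockout 1 or knockout 2 (limma adjusted p = 0.0601, 0.0643, 0.102 and 0.0724). Of 2 tested lymphocyte markers 0 passed in limma, also 0 at an unadjusted p under 0.05 and 0 in edgeR and DESeq2. Lck, the more abundant, stood at 57.1 ± 1.51 in control and 60.8 ± 12.6 in knockout. Of 15 mitochondrially encoded genes 5 rose and 5 fell (adjusted p = 0.591), against 4 and 7 in edgeR, and of 20 replication-dependent histone genes, whose mRNAs lack polyA tails, 1 rose and 1 fell (adjusted p = 0.662).

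The changes were not spread evenly over the genome. In an examination chosen after the data were seen, chromosome 10 had a median log2 change of -0.58 over 690 tested genes, of which 586 fell and 26 rose in limma. Lowered medians also marked chromosome 3 from 3.8 to 115.9 Mb (-0.31), chromosome 9 from 54.5 to 124.5 Mb (-0.30), chromosome 13 from 24.6 to 75.8 Mb (-0.30) and chromosome 15 from 32.2 to 103.5 Mb (-0.22). Chromosome 17 from 3 to 27 Mb had a raised median (0.49), with 165 of 222 genes higher and 11 lower. The chromosome 10 median was -0.58, -0.56 and -0.59 in the 3 knockout libraries against the control mean, and -0.004, -0.02 and 0.02 in the control libraries each against the other 2. These were the 6 of 29 segments with a median of at least 0.2 in size. They held 2852 tested genes, of which 75.7% changed, against 60.1% of genes elsewhere, where the median was 0.08. Chromosome 6 from 3.3 to 21.9 Mb was also lowered (-0.17, with 37 genes lower and 13 higher) but fell short of that size and was counted as elsewhere. Spp1 on chromosome 5 lay outside the 6 segments. Elsewhere 207 genes rose and 558 fell by 2-fold or more.

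**Figure D4:**
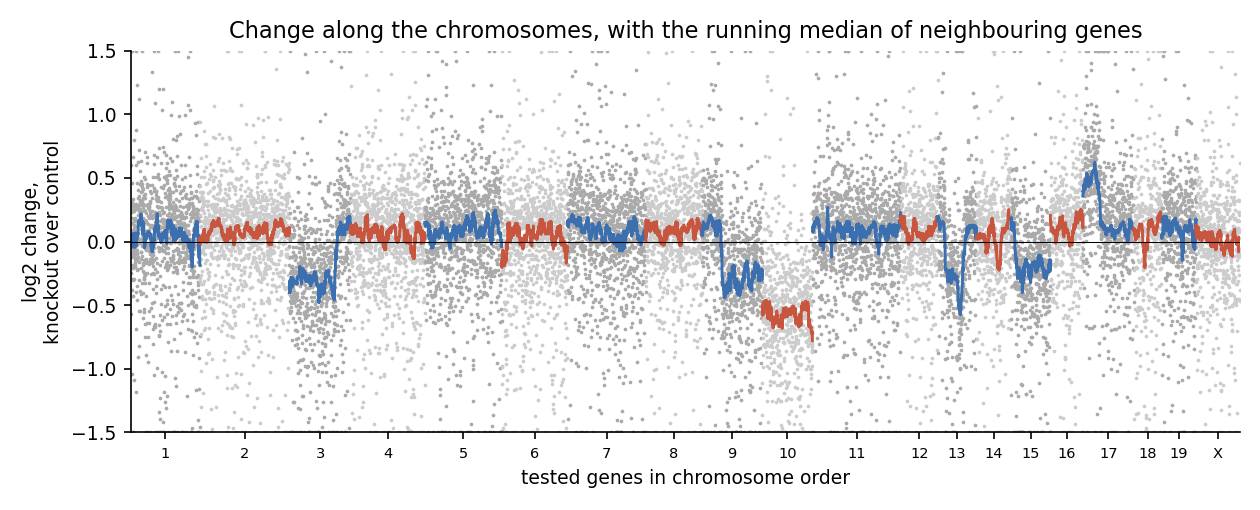
Log2 change of knockout over control (vertical axis, points beyond 1.5 drawn at the edge) for tested genes in order along chromosomes 1 to 19 and X (horizontal axis), 1 grey point per gene, with lines for the median of the 25 tested genes on each side. The median was -0.58 on chromosome 10, 0.49 at the start of chromosome 17 and 0.08 outside the shifted segments.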

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

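The tests on recovered reads of 5 libraries, the positional and trend corrections and the test against 1.2-fold were chosen after the data were seen, as was the use of the estimated correlation, run beside the main test by design, as an alternative count. The edgeR and DESeq2 tests on 6 libraries set beforehand were not run. The Spp1 level remained lower and past the threshold in every alternative run on it. Leaving out 1 library at a time gave 8929 to 9491 genes changed, 4858 to 5241 genes higher in knockout, 4068 to 4250 genes lower in knockout, 1078 to 1113 genes changed at least 2-fold, 8 for gene lists shifted, and -5.64 to -5.28 for the Spp1 level. Apart from the values named next, every count of genes or lists stayed within 1.5 times its main value. A minimum of 50 scaled reads gave 695 genes changed at least 2-fold in place of 1084, with 12593 genes tested in place of 15307. The test against 1.2-fold gave 3749 genes changed, 1581 higher and 2168 lower, since smaller changes are excluded by its construction. Camera with an estimated correlation passed 0 lists in place of 8, with 3 at an unadjusted p under 0.05. More genes were higher than lower except in the test against 1.2-fold, with equal totals (4476 and 5030) and in edgeR (4280 and 4569), and the median of all tested genes moved from 0.03 to -0.02 with equal totals. edgeR called 8849 genes and DESeq2 called 8123, and 8481 of edgeR's calls were also limma's, 0 of them in the other direction. Deviations of same-numbered libraries correlated at -0.107, -0.244 and -0.038 across genes, and no library's highest correlation was with its own number. This gives no sign that the numbers pair the samples, but a weak shared effect could be missed. With the replicate block 9289 genes changed, 5058 higher and 4231 lower, 1086 at least 2-fold, with 8 lists and the Spp1 level at -5.41.

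Subtracting the positional median turned the direction of 6 named genes: Dusp1 (to -0.031), Prim1 (to 0.30), Tipin (to 0.018), Acat2 (to -0.30), Aifm2 (to 0.032) and Hexa (to 0.044). The size of the subtracted median accounts for each by construction. Of the 7476 genes called with and without this correction, 369 changed direction. Over 142 named genes and 20 alternatives 73 single calls were lost, most often for Plvap, H2-M3, mt-Rnr1, Hist1h1c and Esrp1, and the cause was not tested. Without 1 library the calls of mt-Rnr1 (limma adjusted p = 0.0650 to 0.112), mt-Atp6 (0.0540 to 0.0757, a gene that shares 99.5% of its words with another gene), Hist1h1c (0.0516 and 0.0826) and Bcl3 (0.0633 and 0.0930) were among those lost. MAPK pathway output passed camera with edgeR (adjusted p = 0.0465) and after the positional correction (adjusted p = 0.0225), and MHC class I antigen presentation after the latter (adjusted p = 0.0448). With an estimated correlation in the same settings neither passed (adjusted p = 0.698 for MAPK pathway output in edgeR and 0.732 for both after the correction). The medians of the shifted segments kept their sign in 114 values under alternatives, and 38 moved by more than 1 SD between knockout libraries, mostly with another scaling, with the count tests and with the trend subtracted. They ranged from -0.62 to -0.57 on chromosome 10, -0.36 to -0.30 on 3, -0.35 to -0.29 on 9, -0.35 to -0.29 on 13, -0.28 to -0.21 on 15 and 0.44 to 0.51 on 17. Depth limits genes near 1 read in a group, whose log2 change depends on the pseudocount, and genes with 0 reads in a library, which are not listed.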

Other observations

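The tests of a trend and of copy number on chromosome 10, the tests of shared reads and of chromosome-scale shifts for single genes, the counts over knockout libraries and the count of genes with separated libraries were chosen after the results they measure, or part of them, had been seen. The patterns were found in the same data.

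Glial and Schwann cell genes, a programme related to the neural crest origin of melanocytes, were examined after Mbp and S100b, among others, were seen to be lower. Mbp, myelin basic protein, fell from 7041 ± 113 to 688.7 ± 57.5 scaled reads (SD, n = 3; log2 change -3.36 ± 0.05), and S100b, which lies on chromosome 10, fell by 1.55 on the log2 scale. In a list of other such genes, written before their values were seen, 14 of 21 tested members fell and 4 rose in limma. Gfap fell from 123.8 ± 25.6 to 28.9 ± 6.07, Mal from 271.4 ± 29.7 to 66.6 ± 9.75 and Pmp22 from 6328 ± 44.1 to 3418 ± 96.0. These members were chosen after their values were seen. The median of -0.31 passed the bound of -0.3 set beforehand by a narrow margin (camera p = 0.00394, and p = 0.0342 with an estimated correlation), which suggests a broader fall of this programme without a uniform one. For Piwil2 and Ddx25 the same question was asked of other germline genes. Of 4 other tested germline genes 0 rose and 2 fell in limma, also 0 higher at an unadjusted p under 0.05, with a median of -0.42, so a general rise of germline genes was not seen in the few that could be tested.

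With 6 libraries there are only 10 ways to divide them into 3 and 3, too few for a share under 0.05. The real division gave 9640 genes changed, 5266 higher, 4374 lower and 1084 at least 2-fold, and was the 1 division of 10 to give as many. The highest of the others was 0 in each case, with at most 160 genes at an unadjusted p under 0.05 in limma. Each other division mixes knockout and control libraries, so the group difference widens its spread and made calls of single genes unlikely from the start. For gene lists 5 of the 10 divisions gave 8 or more, and the highest of the others was 15. Among the 8 lists called, the real division gave the smallest camera p of all 10 for interferon-stimulated genes (1.62e-13, against 3.60e-09 for the next), cholesterol synthesis (5.13e-09 against 1.79e-07), p53 targets (0.000414 against 0.00563), cytokines (0.00125 against 0.00718) and, by a narrow margin, immune checkpoint and NK ligands (0.000661 against 0.000943). These p come from the preset correlation, and with an estimated correlation none of the 5 lists passed in the real division (camera adjusted p = 0.389, 0.495, 0.389, 0.389 and 0.495). The 8 lists were picked by this same p in the real division, so its rank among the divisions gives no separate support for them. For hypoxia and glycolysis 5 divisions, for epithelial-mesenchymal transition 3 and for S phase 2 gave a p as small, the real one included.

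The chromosome-wide shifts do not follow from a trend on GC content, transcript length or expression, since chromosome 10 still lay at -0.63 against all tested genes after such a trend was subtracted. A difference in copy number between the populations stays open, since no DNA was measured. In 3 groups of chromosome 10 genes of equal size by expression, 85.7%, 97.4% and 96.5% lay below the median of all tested genes, which decides nothing, because with 93.2% of all chromosome 10 genes below it no group could have fallen under 79.6%. Whether the shifts came with the loss of Spp1 or arose for another reason cannot be told apart, because all 3 knockout libraries with the shift carry the same knockout label and the sources do not say if they share a founder.

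The fall of interferon-stimulated genes is not explained by members lying in shifted segments. The median of the list was -1.14 after the running median of neighbouring genes was subtracted (camera adjusted p = 4.23e-15, and adjusted p = 0.264 with an estimated correlation). It was -0.91 after the trend on GC content, length and expression was subtracted (camera adjusted p = 3.96e-11, and adjusted p = 0.434 with an estimated correlation). Only 1 tested member lies on chromosome 10. Subtracting the neighbours' median removes only the local shift of each member. Whether changed genes in the shifted segments lowered members elsewhere therefore stays open. An effect of Spp1 loss and a difference between the cell populations unrelated to Spp1 cannot be told apart, since the median lay below -0.5 in all 3 knockout libraries and the design holds 1 knockout and 1 control condition. No separately made knockout line and no restored Spp1 is in the data.

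The chromosome-scale shifts were too small to explain the 89 genes changed by at least 8-fold. The running median beside them was at most 0.59 in size, against log2 changes of at least 3.01, and it reached 50% of the gene's own change for 0% of the 88 with enough neighbours. Shared sequence does not explain them as a group, since 10.1% of the 89 shared over 20% of their sequence words or exon length with another gene. In all 89 every knockout library lay on one side of every control library. Differences of this size in genes such as Gdf9, Tmem98 and Piwil2 may reflect the history of the knockout population as well as Spp1, and these cannot be told apart with 1 knockout and 1 control condition.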
